A study of Mus musculus with 6 samples.

How the data were processed

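RNA sequencing libraries of 6 samples of mouse HOXB-8 cells were analysed, 3 labelled Parental and 3 labelled IRF2_KO. Groups were taken from the group label of each sample. The labels give no replicate number, batch or date, so replicates are numbered in the order of their records and pair nothing. Per the labels' protocols, RNA was purified on columns with DNase digestion and libraries were made with a stranded total RNA kit, while the molecule label names polyadenylated RNA; which applies was not settled here. Libraries of total RNA and of polyadenylated RNA differ in how much non-coding, histone and unspliced RNA they hold, so levels of such RNAs depend on it.

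The authors aligned the reads with GSNAP to GRCm38, per the submitters' processing notes. Versions and the gene annotation are not given in the sources used here, nor whether strand was used in counting. Per the file headers, the deposited counts are whole numbers of reads aligned uniquely to each gene model, listed by Entrez gene ID. Reads that match several places are therefore absent, which lowers genes with near-identical copies or pseudogenes. Per the file headers, the authors also deposited a size-factor-adjusted RPKM for each gene. These RPKM values were used for a check only: the ratio of RPKM to count differed between libraries by a single factor per library over 10969 genes, so they hold the same counts rescaled.

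The tables list 36528 gene IDs. Symbols and coordinates came from a RefSeq gene table of the same build for 31049 IDs, and names from GENCODE M21 for another 77. The remaining 5402 IDs, which took 1.85% to 1.91% of the counts, stayed in the tests without a name, and 182 of 716 tested IDs of this kind were called. Of 484 list members, 482 were matched.

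The total count was 39011542, 33422590 and 39925038 in the Parental libraries and 29994755, 29070160 and 34051219 in the IRF2_KO libraries, so that 3 counts correspond to 0.0751 to 0.103 CPM. The 10 genes with the most counts took 3.46% to 3.96% of a library. Libraries of a group were compared pair by pair. The mean chi-square per gene, over genes with 20 or more reads in the pair, was 2.78 to 10.1 within groups, above the sampling noise value of 1, and 63.7 to 73.4 between groups. No pair was treated as a repeat of another library.

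Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr (13353 genes), libraries were scaled by TMM (factors 0.987 to 1.02), and the groups were compared with the robust quasi-likelihood F-test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 0.0444. Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. Where a group had 1 to 3 reads of a gene, the ratio of summed reads is given with a 95% exact binomial (Clopper-Pearson) interval, and where it had none the fold is a lower bound against 3 reads over the group.

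Fixed before the data were examined were the design, the alternatives, 30 gene lists and the rule for named genes. That rule names Irf2 and Gsdmd, then the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 CPM whose groups do not overlap, and up to 4 members of each list with the smallest adjusted p. Any other gene was named after its values were seen, and some genes that the rule names are not reported here. Lists with at least 5 tested members (25 of 30) were tested with camera in limma 3.58.1 on log-CPM with a prior count of 2 and a preset correlation of 0.01. In all, 119 list genes were too low to test. Members are also counted with p-values adjusted over the list alone, and camera was repeated with an estimated correlation.

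The alternatives were RLE and upper-quartile factors, library size alone, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, an adjusted p under 0.01, glmTreat against 1.5-fold, a minimum of 2-fold, removal of the 100 most abundant genes, each library left out in turn, and for lists fry and ranks.

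The gene test was tested on simulated data with the real means, dispersions and library sizes, in which 13217 genes passed the filter. It called 70.0% of 50 genes changed 1.25-fold, 77.6% of 49 changed 1.5-fold, 89.8% of 49 changed 2-fold and all 49 changed 4-fold, and 5.14% of its calls were false. With no gene changed it called 0 genes. In a simulation with the lysosome list raised, camera called that list and no other of 25. Genes were drawn independently there, while the correlation estimated for the lysosome list was 0.178. The simulation therefore cannot show how often camera calls lists falsely where members are correlated. For chromosomes, fold changes of 12603 genes were shuffled and chromosome 7 was raised by 0.14, and the shift recovered was 0.141. There 1 other chromosome was also called, and 0 with no shift added. Shuffling removes any likeness between neighbouring genes, so this simulation cannot show what such likeness does to the p-values.

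For the closing section, the median fold change of each of 20 chromosomes was set against that of the other genes with 10000 permutations of genes. GC content and length came from the longest GENCODE M21 transcript of each gene, available for 90.8% of genes with a position, and their trend was removed by loess with a span of 0.5. Figures were drawn with matplotlib 3.10.9.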

Results

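Transcript levels were measured by RNA sequencing in a mouse bone marrow line of HOXB-8 cells, myeloid progenitors that a homeobox transcription factor keeps dividing. The extraction notes also call these lines iMACs. The 6 libraries formed 2 groups of 3. The group labelled Parental is Irf2 wild type, and the extraction notes give its control guide RNA as Luc. The group labelled IRF2_KO received a guide RNA against Irf2, which encodes a transcription factor of the interferon regulatory factor family. The total count per library lay between 33422590 and 39925038 in Parental and between 29070160 and 34051219 in IRF2_KO. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Levels are in CPM, the count of a gene scaled to a common library total after TMM adjustment, given as mean ± SD with n = 3 libraries per group, and positions are on GRCm38.

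The comparison of IRF2_KO with Parental asks which transcripts depend on IRF2. Irf2 itself (Entrez gene 16363, chromosome 8, 46739745 to 46847458) stood at 41.1, 42.4 and 41.1 CPM in the Parental libraries and at 40.3, 37.0 and 40.1 CPM in the IRF2_KO libraries. Its log2 fold change of -0.08 (SE 0.05) did not pass the test (edgeR adjusted p = 0.209). A guide RNA can disrupt a coding sequence without lowering its transcript, and counts per gene hold no bases at the cut site, so the Irf2 level does not check the labels. Gsdmd, which encodes gasdermin D, the pore-forming protein of pyroptotic cell death, fell 33.1-fold, from 74.6 ± 5.09 to 2.25 ± 0.271 CPM (edgeR adjusted p = 5.59e-18). Interferon-stimulated genes such as Oas3 and Rsad2, near silent in Parental, rose, while Tap2 and Psmb9, which serve the supply of peptides to MHC class I molecules, fell.

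Of 13353 genes tested, 3146 were higher and 3150 lower in IRF2_KO (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), which is 47.2% of those tested. Most of these differences were small, and the median absolute log2 fold change of a called gene was 0.32. Genes that changed 2-fold or more were more often higher (640) than lower (302).

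The 10 genes with the largest rises were taken by the fixed rule. Rtp4 (chromosome 16, 23520219 to 23614222), an interferon-induced receptor transporter protein, had 1 read over the Parental libraries and 3113 over the IRF2_KO libraries, a ratio of 3838 with a 95% counting interval of 688 to 151626. Oas2 (chromosome 5, 120730333 to 120749886), an oligoadenylate synthetase that activates RNA decay, had 3 reads against 5001, a ratio of 2055 with an interval of 703 to 9968. Xaf1, an interferon-induced regulator of apoptosis, had no read in Parental and 385 in IRF2_KO, at least 158-fold higher against a floor of 3 reads over the group. Such intervals and floors cover counting error only. Oas3 rose from 0.186 ± 0.0323 to 108 ± 3.49 CPM, and Rsad2, which encodes viperin, rose by 8.42 on the log2 scale (SE 0.11). The guanylate-binding protein genes Gbp2 and Gbp5, in a cluster on chromosome 3, rose by 7.75 and 7.72 on the log2 scale (SE 0.13 and 0.09). Oas1a and Oas1g rose by 9.04 and 7.28, and Armh4 by 6.97. Oas1a and Oas1g are close paralogs, and only uniquely aligned reads were counted, so how reads divide between such copies is uncertain.

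**Figure D1:**
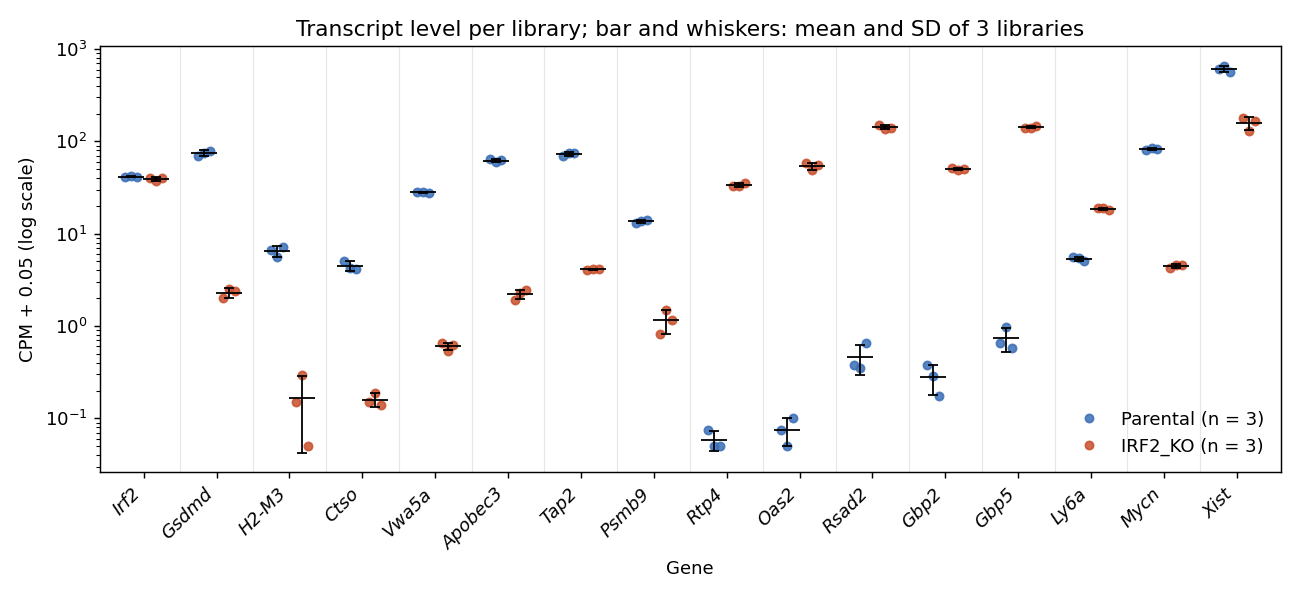
CPM plus 0.05 on a log axis for 16 genes, with a point per library, Parental in blue and IRF2_KO in red, and a bar with whiskers for the mean and SD of 3 libraries. Irf2 lies near 40 CPM in both groups (41.5 and 39.1), Gsdmd lies at 74.6 CPM in Parental and 2.25 CPM in IRF2_KO, and Rsad2 lies at 0.407 and 143 CPM.

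The 10 genes with the largest falls were taken by the same rule. H2-M3 (chromosome 17, 37270234 to 37274485), a non-classical MHC class I molecule that presents formylated peptides, fell from 6.46 ± 0.862 to 0.115 ± 0.123 CPM (log2 fold change -5.85, SE 0.31). Vwa5a fell from 28.0 ± 0.616 to 0.553 ± 0.0592 CPM, and Ctso, a cysteine cathepsin, from 4.45 ± 0.525 to 0.110 ± 0.0263 CPM. Apobec3 (chromosome 15, 79892058 to 79918218), a cytidine deaminase that restricts retroviruses, fell from 61.7 ± 2.46 to 2.16 ± 0.255 CPM. The other members of this set were Gsdmd, Akap2 (log2 fold change -4.98), Hfe (-4.83), Col9a1 (-4.70), Cpq (-4.70) and Slfn9 (-4.62). Hfe encodes an MHC class I-like regulator of iron uptake.

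Among the interferon-stimulated genes, 28 of 32 tested members rose, 1 fell and 3 did not pass the test (28 and 1 adjusted over the list alone). The median log2 fold change was 4.57, and 4.53 with the 3 members that had no Parental read set at their lower bound. Against all other genes the list was higher (camera adjusted p = 4.39e-17), and it was the only list still called with an estimated correlation (adjusted p = 0.0138 with an estimated correlation). Usp18, which removes the ubiquitin-like modifier ISG15 from proteins, rose from 0.740 ± 0.151 to 52.6 ± 1.76 CPM. Parp14 was the member that fell, from 12.1 to 4.13 CPM, and Herc6, Dhx58 and Cxcl10 did not pass the test (log2 fold changes -0.05, 0.04 and 0.22). Markers of macrophages, described further on, were also higher in the IRF2_KO libraries, and at least 1 of them, Siglec1, is itself induced by interferon.

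Interferon-inducible GTPases, which attack vacuoles that hold pathogens, rose in 11 of 12 tested members and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 7.27e-08). The call did not hold with an estimated correlation (adjusted p = 0.0522 with an estimated correlation). Gbp7 rose from 22.9 ± 1.03 to 537 ± 35.0 CPM and Gbp3 from 1.13 ± 0.127 to 118 ± 1.37 CPM. Gbp4 was the member that fell, by 0.23 on the log2 scale.

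MHC class I presentation genes fell in 13 of 19 tested members, rose in 4 and did not pass in 2 (14 fell and 5 rose adjusted over the list alone). The list was lower than other genes (camera adjusted p = 0.000809), though not with an estimated correlation (adjusted p = 0.200 with an estimated correlation). Tap2, a subunit of the transporter that carries peptides into the endoplasmic reticulum, fell from 73.3 ± 3.24 to 4.06 ± 0.0259 CPM (log2 fold change -4.17, SE 0.07). Tapbpl, a peptide editor of class I molecules, fell from 25.7 ± 1.63 to 1.61 ± 0.288 CPM, and Psmb9, an immunoproteasome subunit, from 13.5 ± 0.526 to 1.10 ± 0.328 CPM. The class I heavy chain gene H2-D1 fell from 217 ± 7.40 to 90.5 ± 4.56 CPM. The members that rose were B2m, the class I light chain (log2 fold change 0.38), Tapbp (0.67), H2-T22 (1.01) and H2-T23 (1.37). Class I heavy chains are a family of similar genes, so their counts are uncertain where reads could align to several members. For MHC class II presentation, 2 of 6 tested members rose, Ctss and Cd74, none fell and 4 did not pass (2 and 0 adjusted over the list alone), and the list was not called (camera adjusted p = 0.545). Its median log2 fold change of -0.01 differed in sign from its mean of 0.36.

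The IRF family and interferon signalling list rose in 14 of 21 tested members and fell in 3, with the same counts adjusted over the list alone (camera adjusted p = 0.000425). With an estimated correlation it was not called (adjusted p = 0.158 with an estimated correlation). Irf9, part of the complex that drives interferon-stimulated genes, rose from 7.42 ± 0.265 to 40.6 ± 0.785 CPM and Irf7 from 0.487 ± 0.0776 to 9.21 ± 1.39 CPM. Irf7 and Stat2 are among the members that also belong to the list of interferon-stimulated genes. In Toll-like receptor signalling, 9 of 18 tested members rose and 2 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0265, and adjusted p = 0.164 with an estimated correlation). Tlr13, a sensor of bacterial ribosomal RNA, rose from 2.58 ± 0.269 to 14.1 ± 0.379 CPM, whereas Cd14, a lipopolysaccharide co-receptor, fell from 58.0 ± 1.18 to 29.3 ± 0.877 CPM. Of the inflammatory cytokine and chemokine genes, 5 of 13 tested rose and 3 fell, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.486). Ccl6 rose from 37.1 ± 0.418 to 85.0 ± 2.26 CPM, and Csf1 fell from 10.1 ± 0.972 to 5.12 ± 0.229 CPM.

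Pyroptosis and inflammasome genes went both ways: 8 of 17 tested rose and 4 fell, with the same counts adjusted over the list alone, and camera did not call the list (adjusted p = 0.445). Its median log2 fold change was 0.15 and its mean -0.13, and the rotation test fry, which asks whether the members move on balance, called it lower (adjusted p = 0.00324). Besides Gsdmd, the inflammasome adaptor Pycard fell, from 55.9 ± 2.80 CPM in Parental, with a log2 fold change of -2.00 (SE 0.06). Casp4, the caspase that senses cytosolic lipopolysaccharide, rose from 16.4 ± 0.933 to 37.1 ± 0.845 CPM, and P2rx7, an ATP-gated channel, from 2.49 ± 0.187 to 8.73 ± 0.0834 CPM. Apoptosis and necroptosis genes rose in 14 of 21 tested members and fell in 3, with the same counts adjusted over the list alone (camera adjusted p = 0.0265, and adjusted p = 0.164 with an estimated correlation). Zbp1, a nucleic acid sensor upstream of necroptosis that is also in the interferon-stimulated list, rose from 1.73 ± 0.319 to 57.8 ± 1.79 CPM, and Casp8, an initiator caspase that restrains necroptosis, from 119 ± 1.71 to 148 ± 0.832 CPM. These lists mix genes that promote and genes that restrain cell death, among them Mcl1 and Cflar, which restrain it and rose by 0.42 and 0.34.

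Macrophage markers rose in 13 of 17 tested members and fell in 1, with the same counts adjusted over the list alone (camera adjusted p = 7.76e-07). That call was lost with an estimated correlation (adjusted p = 0.0522 with an estimated correlation). Lpl, a lipoprotein lipase, rose from 71.8 ± 1.23 to 472 ± 15.0 CPM, Lyz2 from 193 ± 5.43 to 480 ± 9.97 CPM and Csf1r, the macrophage growth factor receptor, from 4.62 ± 0.0535 to 18.0 ± 0.959 CPM. Cd14 was the member that fell, by 0.99 on the log2 scale, and Apoe, Mertk and Spi1 did not pass the test (log2 fold changes 0.10, 0.42 and 0.03). Cd163, too low to test, had 11, 2 and 10 reads in the Parental libraries and none in IRF2_KO. The complement genes C1qa, C1qb and C1qc had at most 1 read in any library. Neutrophil and granule markers went both ways, with 9 of 20 higher and 5 lower, the same counts adjusted over the list alone, and no call for the list (camera adjusted p = 0.445). Elane, neutrophil elastase, fell from 2989 ± 98.9 to 924 ± 72.2 CPM and Ltf, lactoferrin, rose from 6.39 ± 0.987 to 16.6 ± 0.359 CPM. Dendritic cell markers rose in 5 of 7 tested members and fell in 2, with the same counts adjusted over the list alone (camera adjusted p = 0.217). Clec10a rose from 14.7 ± 0.288 to 36.3 ± 2.50 CPM and Flt3 fell from 17.7 ± 0.699 to 9.83 ± 1.18 CPM.

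Among haematopoietic progenitor markers, 3 of 6 tested members fell and 1 rose, with the same counts adjusted over the list alone, and the list was not called (camera adjusted p = 0.342). Mycn fell from 82.7 ± 1.49 to 4.42 ± 0.188 CPM, and Kit, the stem cell factor receptor, from 8.04 ± 0.145 to 0.827 ± 0.181 CPM. Myb fell from 644 ± 2.87 to 474 ± 9.57 CPM, and the surface antigen gene Ly6a rose from 5.32 ± 0.281 to 18.6 ± 0.437 CPM. Hoxb8 had a log2 fold change of 0.09 that did not pass the test (edgeR adjusted p = 0.142). Cell cycle genes differed little, with 3 of 22 higher, 4 lower and 15 not passing, the same counts adjusted over the list alone (camera adjusted p = 0.505).

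Cholesterol synthesis genes fell in 15 of 19 tested members, rose in 1 and did not pass in 3 (16 fell adjusted over the list alone; camera adjusted p = 3.41e-05). The call was not kept with an estimated correlation (adjusted p = 0.0522 with an estimated correlation). Lss, lanosterol synthase, fell from 193 ± 4.59 to 137 ± 2.55 CPM and Cyp51, lanosterol demethylase, from 162 ± 9.15 to 120 ± 4.27 CPM. Glycolysis and hypoxia genes rose in 14 of 16 members and none fell, with the same counts adjusted over the list alone (camera adjusted p = 1.32e-05, and adjusted p = 0.180 with an estimated correlation). Gpi1 rose from 528 ± 28.1 to 773 ± 40.9 CPM and Pgk1 from 91.5 ± 8.48 to 148 ± 7.69 CPM. The members that did not pass, Gapdh and Pgam1, had only 4.37 and 3.39 CPM in Parental, levels that are uncertain because reads shared with pseudogene copies do not align uniquely. Lysosome genes rose in 14 of 16 tested members and none fell, with the same counts adjusted over the list alone (camera adjusted p = 2.20e-06, and adjusted p = 0.164 with an estimated correlation). Atp6v0d2, a subunit of the proton pump, rose from 2.77 ± 0.557 to 11.5 ± 0.766 CPM and the protease gene Ctsb from 390 ± 14.3 to 583 ± 10.5 CPM. Macrophage markers were higher in the same libraries (13 of 17, Gpnmb by 1.53 on the log2 scale), as they were beside each other list called higher. Targets of p53 rose in 7 of 10 tested members and none fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0138, and adjusted p = 0.200 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 251 ± 7.40 to 474 ± 16.0 CPM.

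Lists of other stress and lipid genes were not called. Lipid efflux genes and targets of the LXR receptors had 4 of 12 higher and 2 lower (camera adjusted p = 0.486), with a median log2 fold change of -0.06 and a mean of 0.24; the fatty acid transporter Cd36 rose from 4.45 ± 0.294 to 15.2 ± 1.02 CPM. Oxidative stress genes had 2 of 9 higher and 3 lower (camera adjusted p = 0.486), with Hmox1, haem oxygenase, rising from 69.6 ± 2.82 to 171 ± 10.1 CPM. Endoplasmic reticulum stress genes had 1 of 11 higher and 4 lower (camera adjusted p = 0.445). For these 3 lists the counts adjusted over the list alone were the same. Immediate early and heat shock genes had 4 of 9 higher and none lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.473), among them Jun and Fos (log2 fold change 0.88 for both). The other 2 calls were fragile: that of Nr4a1 (log2 fold change 0.87) was lost with DESeq2 and without Parental 1, Parental 2, IRF2_KO 1 or IRF2_KO 3 (0.72 to 1.08 over all alternatives), and that of Egr1 (0.27) without Parental 1, Parental 3 or IRF2_KO 3 (0.20 to 0.36).

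Signs of RNA recovery and of other cell types were read from further lists. Mitochondrial transcripts took 0.710% to 0.855% of the counts per library. This share is uncertain, as reads that match several places were not counted. In Parental mt-Co2 had only 0.278 CPM against 1898 CPM for mt-Nd1, and mt-Co3 and mt-Atp6 had at most 9 and 13 reads in any library. On the log2 scale mt-Nd1 fell by 0.48, mt-Co1 rose by 0.29 and the other 5 tested did not pass (camera adjusted p = 0.783). Abundant non-coding RNAs had 1 of 5 higher, Neat1, and 1 lower, Rpph1 (camera adjusted p = 0.718), and replication-dependent histones 1 of 6 higher and none lower (camera adjusted p = 0.473). That histone call, H4c9 (log2 fold change 0.35), was lost without Parental 2 (0.29, adjusted p = 0.0565, against 0.00153 for the lowest of its alternatives). In these 3 lists the counts adjusted over the list alone were the same. Markers of other lineages were sparse, with fewer than 5 members tested per list and so no list test. Of mast cell, basophil and eosinophil markers, Ms4a2 and Mcpt8 were tested and neither passed. Of lymphoid markers, Ebf1 fell from 3.53 ± 0.195 to 0.352 ± 0.137 CPM and Nkg7 from 0.952 ± 0.133 to 0.567 ± 0.155 CPM, the latter a call lost in 5 alternatives, DESeq2 and leaving out Parental 2, Parental 3, IRF2_KO 1 or IRF2_KO 2 (adjusted p = 0.0209 to 0.138 over all alternatives). Of erythroid and megakaryocyte markers, Gp1bb rose from 8.20 ± 0.465 to 20.8 ± 1.63 CPM, and of stromal and endothelial markers Thy1 fell and Pecam1 rose, both near 1 CPM or below. In the sex-linked check, Xist, the RNA that silences an X chromosome, fell from 609 ± 48.1 to 158 ± 25.7 CPM (log2 fold change -1.95, SE 0.12, edgeR adjusted p = 4.76e-06), and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had at most 1 read in any library.

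**Figure D2:**
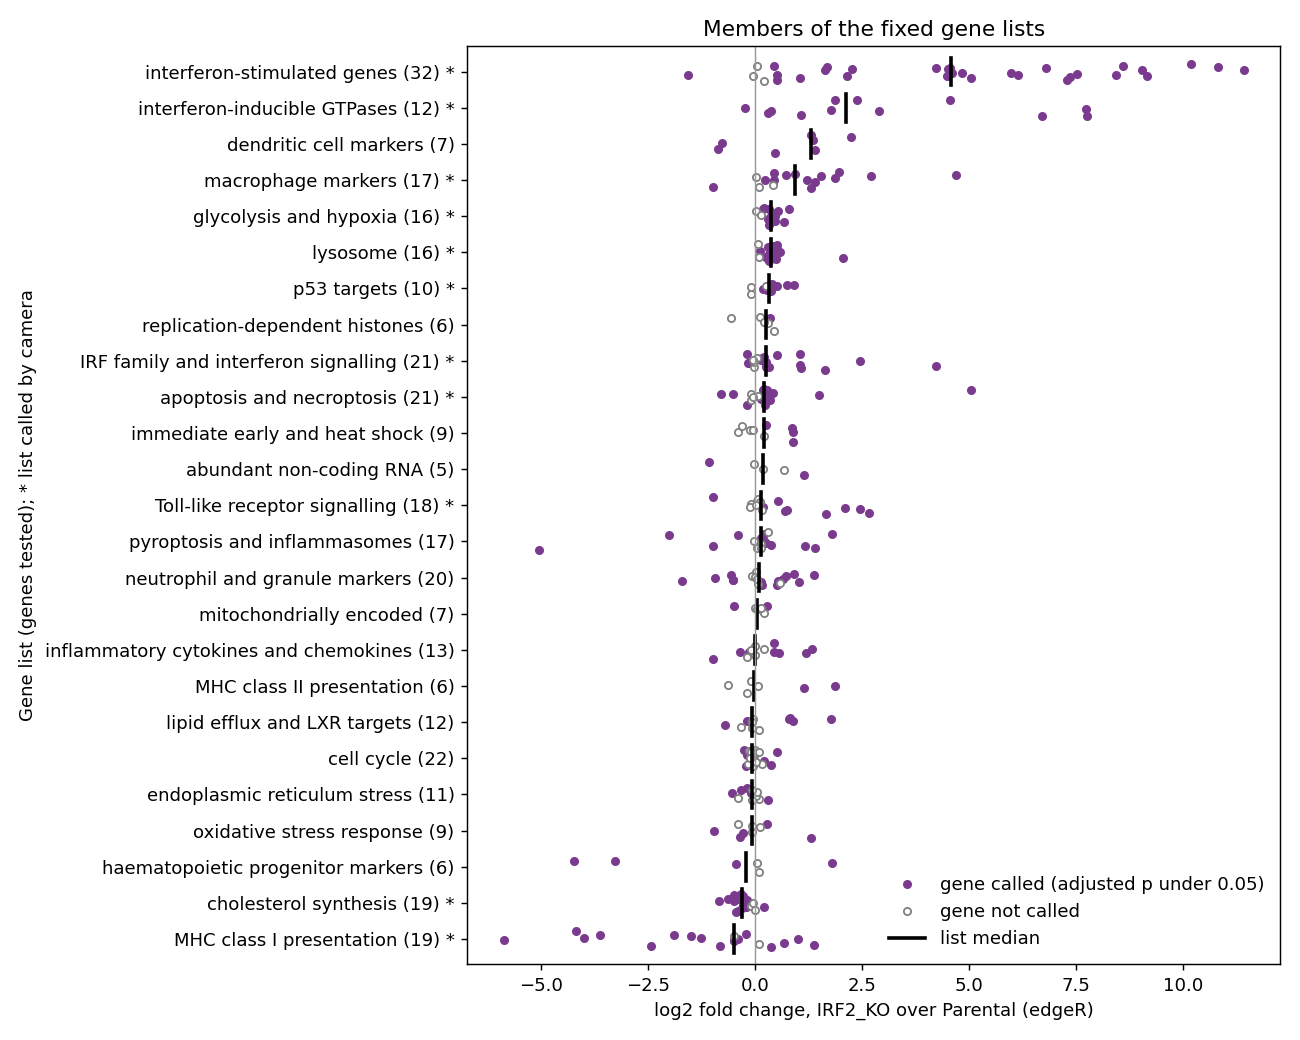
The log2 fold change of IRF2_KO over Parental for each tested member of the 25 gene lists with 5 or more tested members. Filled points are called genes, open points are not called, black bars are list medians, and a star marks the 11 lists called by camera. The interferon-stimulated genes have the highest median (4.57) and MHC class I presentation the lowest (-0.50).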

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

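No gene called both in the main test and in any of its 17 alternatives changed direction. An adjusted p under 0.01, glmTreat and the 2-fold minimum keep the fold changes of the main fit, so they could not change a direction. The counts of higher and lower genes were 718 and 301 with glmTreat against 1.5-fold and 640 and 302 with a 2-fold minimum; both demand a larger effect, which removes small changes. Leaving out 1 library gave 2717 to 3158 higher and 2539 to 3099 lower genes, and DESeq2 gave 2898 and 2758. With library size alone 42.8% of calls were higher and the median of inflammatory cytokines and chemokines, a list not called, changed sign, and no scaling moved the median of all genes by over 0.1. Gsdmd lay between -5.12 and -4.95 and Irf2, never called, between -0.10 and -0.05 with 1 library left out. Camera called 11 lists with each library left out and 1 (interferon-stimulated genes) with an estimated correlation. The test fry called 19, as it does not compare a list with other genes. The estimated correlation lay below the preset 0.01 for Toll-like receptor signalling (-0.049), apoptosis and necroptosis (-0.036), cholesterol synthesis (-0.015) and macrophage markers (0.006). Higher correlation between members therefore cannot account for the loss of these calls. For interferon-stimulated genes, at an estimated correlation of -0.003, the camera adjusted p also rose, from 4.39e-17 to 0.0138. The estimated setting thus raised p-values even where members were no more correlated than the preset. For the other lists that lost their call the estimated correlation lay above 0.01. How much of their loss came from correlation was not tested. Directions that turned with 1 library left out belonged to results that were not called, and the cause was not tested. Their ranges were -0.074 to 0.022 for the Acta2 log2 fold change, -0.037 to 0.11 for mt-Cytb and -0.052 to 0.18 for Mcpt8. For list medians they were -0.057 to 0.36 for immediate early and heat shock genes, -0.070 to 0.017 for MHC class II presentation, -0.074 to 0.38 for inflammatory cytokines and chemokines, -0.037 to 0.11 for mitochondrially encoded genes and -0.21 to 0.024 for haematopoietic progenitor markers. Other results for single named genes kept direction and side of the threshold in 1579 cases, lost a call in 14 and gained one in 6. The calls lost were those of Nkg7 (without Parental 2 or 3 or IRF2_KO 1 or 2, and with DESeq2), Nr4a1 (without Parental 1 or 2 or IRF2_KO 1 or 3, and with DESeq2), Egr1 (without Parental 1 or 3 or IRF2_KO 3) and H4c9 (without Parental 2), and those gained were of Malat1 and mt-Nd5. No paired analysis was possible because the labels give no replicate numbers. Depth limits genes below about 0.1 CPM, where 3 reads or fewer are seen per library.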

Other observations

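The tests on Malat1 and Neat1, on the X-linked median, on class I presentation genes and on abundant neutrophil and granule markers were chosen only after the results they measure were seen. The genes in this and the next paragraph were brought together after their values were seen, though the fixed rule names Gbp2, Gbp3, Gbp5, Gbp7, Slfn9 and Fasn. Of the called ones only Aim2 lost its call, and none changed direction, with RLE or upper-quartile factors or library size alone. Guanylate-binding protein genes differed by location. The 4 tested on chromosome 3, Gbp2, Gbp3, Gbp5 and Gbp7 (142496934 to 142638008), rose by 4.55 to 7.75 on the log2 scale. The 6 tested on chromosome 5 ranged from -1.16 (Gbp10) to 1.08 (Gbp9). Schlafen genes on chromosome 11 also parted: Slfn8 rose by 4.07, Slfn5 from 3.26 to 52.7 CPM, Slfn1 by 2.85, and Slfn9, which lies between Slfn5 and Slfn8, fell from 21.2 ± 0.990 to 0.869 ± 0.313 CPM (SD, n = 3). The 6 tested Ifi200 genes on chromosome 1 rose by 1.55 (Ifi209) to 5.46 (Ifi206), while Aim2, a DNA sensor gene beside them, had a log2 fold change of only 0.14 (edgeR adjusted p = 0.0466, and 0.0379 to 0.113 over these scalings, the highest with library size alone). These families hold similar paralogs, so the split of reads among members is uncertain.

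Scd1, a stearoyl-CoA desaturase, fell from 631 ± 14.2 to 69.9 ± 0.332 CPM, while its paralog Scd2 stayed uncalled at 4121 ± 53.8 and 3978 ± 125 CPM (log2 fold change -0.05, edgeR adjusted p = 0.319). Fasn and Acaca fell by 0.70 and 0.27, Elovl6 rose by 1.09 and Acly did not pass (0.06). Thrsp, a regulator of lipogenesis, had 197 reads in Parental and 2 in IRF2_KO, a ratio of 79.9 with a 95% counting interval of 21.8 to 664. Cybb, a subunit of the phagocyte NADPH oxidase, rose from 16.5 ± 0.660 to 125 ± 8.56 CPM and Lgals3bp by 4.13 on the log2 scale (SE 0.05). Of the transcription factor genes Zic2 and Sp9, Zic2 rose from 0.0933 ± 0.0601 to 4.93 ± 0.277 CPM and Sp9 from 1.03 ± 0.0658 to 12.0 ± 0.833 CPM.

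The fall of Xist in all 3 IRF2_KO libraries is a first pattern. Weaker recovery of long nuclear RNA is argued against by Malat1 and Neat1, with a mean log2 fold change of 0.91 (SE 0.13). Neat1 rose by 1.14 (SE 0.07), while Malat1 (0.67, SE 0.25) did not pass the test (edgeR adjusted p = 0.0890). Whether either RNA is itself regulated in these cells was not tested. A large rise of X-linked genes is argued against by their median, 0.047 (bootstrap SE 0.016) above the autosomal one. A small rise was called by permutation of genes, which treats them as independent (adjusted p = 0.0174). Among genes with 8 CPM or more it was 0.073 (permutation adjusted p = 0.001). The cause of this small rise was not tested. Genes that escape X inactivation were lower: the median of Ddx3x, Kdm5c, Kdm6a, Eif2s3x, Pbdc1 and Utp14a lay at -0.37 (bootstrap SE 0.10) relative to autosomes, and Utp14a was the member not called. A candidate explanation is loss of the inactive X chromosome in part of the cells, a hypothesis that DNA copy number would test. Whether this came with IRF2 loss or with the history of a single line stays open, as each group may derive from 1 line.

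A second pattern is on chromosome 3, where the median log2 fold change was 0.15 above that of other genes (568 genes, permutation p = 0.0001, the smallest that 10000 permutations can give; adjusted p = 0.002 over 20 chromosomes by Benjamini-Hochberg), and the shift was 0.14 to 0.15 in all 3 IRF2_KO libraries. The pattern was first seen among genes with 8 CPM or more (409 genes, shift 0.14). Among all tested genes 8 other chromosomes, X among them, passed with shifts from -0.05 to 0.05. The permutations treated genes as independent, whereas large changes lay near each other, as described further on, so these p-values may be too small. The chromosome 3 shift stayed at 0.14 (bootstrap SE 0.02) after the trend on GC content and transcript length was removed. This argues against that trend as the whole cause. The shift of 0.14 without the 41 genes changed 2-fold or more decides nothing, as no 41 genes could have taken the median shift below 0.13. Extra copies of the chromosome in part of the cells stay open: 9 of 14 bins of 10 Mb (64.3%) lay above the autosomal median, and 9 of 12 (75.0%) among genes with 8 CPM or more, between the bounds set for and against. Bin medians among all tested genes ranged from -0.10 (110 to 120 Mb) to 0.26 (100 to 110 Mb), in no single block. All bins from 60 to 110 Mb lay above the autosomal median. The highest of these, from 80 to 110 Mb (0.16, 0.20 and 0.26), held 91, 111 and 81 genes. Bins from 30 to 60 Mb lay below the autosomal median (-0.04, -0.03 and -0.02), while those at 10 to 20, 120 to 130 and 140 to 150 Mb lay above. The bin at 150 to 160 Mb (-0.011), counted as above, and that at 130 to 140 Mb (-0.016), counted as below, lay close to that median (-0.013). Gain of a part was not tested.

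A further pattern is that interferon-stimulated genes rose while 13 of 19 tested class I presentation genes, many of which interferon induces, fell and 4 rose, a list call not kept with an estimated correlation (adjusted p = 0.200 with an estimated correlation). Replacement of nearly all cells by a type without the neutrophil and granule markers is argued against by 5 abundant ones (Prtn3, Ctsg, Ms4a3, Mpo and Elane). Their median log2 fold change was -0.077 (bootstrap SE 0.46), against -4.17 for Tap2. That median is the value of Ms4a3, which is not itself a granule gene. Prtn3 and Ctsg lay at 0.08 and 0.13, and Mpo and Elane at -0.52 and -1.69. A change of cell state or of part of the cells stays open, since Elane fell by 1.69, Mpo by 0.52, Kit by 3.26 and Mycn by 4.23, and 13 of 17 macrophage markers rose. Interferon in the cultures cannot be told apart from IRF2 loss without it: the class I median of -0.50 (bootstrap SE 0.48) only repeats the pattern, and these genes could need IRF2 to respond. Reads of 21 interferon genes summed to 3 in Parental and 4 in IRF2_KO, of which Ifnb1 had 0 and 3.

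Large changes lay near each other, a hypothesis tested among all tested genes after a first count at a mean of 1 CPM or more had given a similar share. Of 293 called genes changed 4-fold or more, 27.3% had as nearest tested neighbour a gene called and changed 2-fold or more in the same direction, against a mean of 3.78% and a highest value of 8.19% in 1000 shuffles (permutation p = 0.001, the smallest they can give). In 27 of these 80 cases the neighbours share the part of the name before its first digit, as in the Oas and Gbp clusters. This count leaves out some related or overlapping neighbours, such as Igtp and Irgm2 or Gbp2 and Mir6381. Neighbours that both changed 4-fold or more can each appear as a case, as Oas2 and Oas3 do. Overlapping or similar genes may share reads.

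The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave the most in each case (1 of 10): 3146 higher and 3150 lower genes with edgeR, against a highest of 0 and 0 in the other splits, which had 47 to 516 genes at an unadjusted p under 0.05 and 0 calls with limma-voom. The real split called 11 lists, against a highest of 7 in the others. Each other split put libraries of both groups on either side, so the difference between the groups counted there as spread. Few or no gene calls were thus to be had in them from the start. The other splits therefore do not measure how many genes or lists chance would call, and no conclusion is drawn from them.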
